A study of Rattus norvegicus with 16 samples.

How the data were processed

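Muscle pieces of the tibialis anterior, kept frozen, gave RNA by RNAisoPlus, and its poly-A fraction was caught on poly-T beads, broken up and copied into cDNA from random hexamers, per the labels' protocols. The protocols allow for a directional (dUTP) or a non-directional (dTTP) library and do not say which was made. The strand setting of the counting is not given in the sources used here, so reads of a gene and of an overlapping or antisense gene could not be told apart. HISAT2 2.0.5, featureCounts 1.5.0-p3 and the build mRatBN7.2 are named per the submitters' processing notes. The annotation release, the read filters and the treatment of reads matching several places are not given in the sources used here, so values of close gene copies such as the myosin heavy chains are uncertain.

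The authors deposited 1 table of FPKM values (fragments per kilobase of gene and 1e6 reads) for 31141 rat Ensembl genes in 16 libraries, with each gene's symbol, position, length, strand and type, per the file headers. Each FPKM value multiplied by its gene length was a whole multiple of what 1 read is worth in its library (100% of values within 0.05 of a whole number), which gave back the reads assigned to each gene. The library size behind the values was not the number of assigned reads but that library's median-of-ratios size factor times a common constant, to within 4.8e-10%. The deposited FPKM are therefore already scaled between libraries. Size factors averaged 0.714 ± 0.16 (SD, n = 4) in WT_ND, 1.23 ± 0.137 (n = 6) in DMD_ND and 1.10 ± 0.266 (n = 6) in DMD_KD. In such values a few abundant genes taking more reads do not lower the rest, whereas in TPM they do: the 10 most abundant genes took 31.8 ± 2.7% (SD, n = 4) of WT_ND reads, 19.8 ± 1.19% (n = 6) of DMD_ND and 24.0 ± 2.9% (n = 6) of DMD_KD reads.

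Each library's column was matched to its sample by name, and each sample to its group by its genotype and diet labels. No column was left unmapped. Libraries of a group differed beyond sampling noise (lowest chi-square per degree of freedom 11.7 over genes with at least 20 reads), so none was counted as a repeat of another. The 7743 genes without a symbol were kept in the tests and not named. No reference genome was used, so GC content was not checked, and gene positions are those of the deposited table.

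Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. Genes with at least 1 FPKM in at least 4 libraries were kept, 12119 in all, 11110 of them protein-coding and 1262 without a symbol. A single model of group means was fitted to all 16 libraries, which share 1 estimate of the spread (13 residual degrees of freedom), with eBayes trend and robust options. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the tested genes, and genes with an adjusted p under 0.05 were called. The design assumed values with no further scaling, and the files held that unit. Each comparison is the first group minus the second: DMD_ND against WT_ND, DMD_KD against DMD_ND and DMD_KD against WT_ND.

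Gene lists for the tissue and the diet, 36 with 659 entries of which 532 were measured, were fixed before the data were examined, as were the tests, most of the other settings tried and the rule for naming genes. They cover matrix, inflammation, regeneration, contraction, energy metabolism, stress, time of sampling, sample handling, RNA quality and markers of other cell types that muscle holds. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, with an estimated correlation and fry as alternatives. Fry tests whether a list's genes move on balance one way and does not compare them with other genes. Members were also adjusted over the list alone. The rule named Dmd; the 8 largest rises and 8 largest falls among called genes with a proper symbol and a mean of at least 5 FPKM in the higher group; per list described, up to 4 members with the smallest p and the called member with the largest fold change; and, with fewer than 10 calls, the 10 genes with the smallest p under the same conditions. Genes named for DMD_KD against WT_ND come from the other comparisons. Some genes that the rule selects are not reported here.

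Library measures were compared by exact permutation tests over all relabellings. The relation of diet and genotype fold changes was set against 100 drawn and all 924 relabellings of the mutant libraries, against simulated unchanged groups made from sign-flipped residuals (100 draws), and against the 20 ordered splits of DMD_ND into 3 and 3 libraries. Other splits of the libraries were fitted 100 times per comparison. List medians left after the genotype multiple were also set against the largest of all lists in each relabelling, each scaled by its spread, a test added after seeing the data.

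The test was tried on simulated data with known changes in a small set of the 12119 genes. Noise was drawn independently per gene, with 1 spread for all groups and no outlying library, unlike the real data. The planted changes also ease the adjusted cutoff, so where few genes are called, as for the diet, recovery can be lower than given here. For DMD_KD against DMD_ND it recovered 59.7% of 67 genes changed 1.5-fold, 89.6% of 67 changed 2-fold and 93.9% of 66 changed 4-fold, and 6.36% of its calls were false. For DMD_ND against WT_ND the shares were 43.3%, 83.6% and 93.9%, with 3.92% false, and for DMD_KD against WT_ND 44.8%, 85.1% and 93.9%, with 5.1% false. A single gene list given a shift was called by camera, and 0 of the other lists were.

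Other settings fixed at that point were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-of-ratios scaling over the tested genes, TPM, only both groups compared, the replicate number as a block, eBayes without its options, weights per library, a 2-fold threshold, an exact rank-sum test and leaving out each library in turn. Limma voom on the recovered reads, plain FPKM per 1e6 assigned reads and leaving out libraries that stood apart were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.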

Results

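Messenger RNA from the tibialis anterior muscle of Wistar-Imamichi rats was sequenced in 16 libraries. Dmd encodes dystrophin, the protein that links the muscle fibre's cytoskeleton to the surrounding matrix, and its loss causes Duchenne muscular dystrophy. Of the libraries, 6 came from Dmd-mutant rats fed the MCTKD diet (DMD_KD), 6 from Dmd-mutant rats on a normal diet (DMD_ND) and 4 from wild-type rats on the normal diet (WT_ND). The labels do not spell out MCTKD, which in nutrition research commonly stands for a medium-chain triglyceride ketogenic diet. The diets ran from weaning to an age of 9 months. Between 17125084 and 28116085 reads per library were assigned to genes, with means of 21660000 ± 2440000 (SD, n = 4) in WT_ND, 20360000 ± 2190000 (n = 6) in DMD_ND and 21320000 ± 3770000 (n = 6) in DMD_KD. Values are FPKM as deposited, and fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. The labels do not state that each library came from a separate animal, so the p-values measure the spread between these samples, which may in part be technical.

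Dmd transcripts were lower in every mutant library than in every wild-type library. The gene (ENSRNOG00000046366) spans chromosome X, 47272331 to 49504207, in mRatBN7.2 as the deposited table gives it. Its level was 7.32 ± 3.32 FPKM (SD, n = 4) in WT_ND, 1.76 ± 0.209 (n = 6) in DMD_ND and 1.36 ± 0.545 (n = 6) in DMD_KD. DMD_ND was lower than WT_ND by a log2 fold change of -1.51 (SE 0.21, limma adjusted p = 7.73e-06) and DMD_KD by -1.77 (SE 0.21, adjusted p = 2.24e-06). DMD_KD and DMD_ND differed by -0.26 (SE 0.19), which did not pass the test (adjusted p = 0.501).

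Genotype separated the libraries most. The first principal component of the 12119 tested genes held 67.8% of the variance and put WT_ND between 63 and 80.9, DMD_ND between -45.1 and -26.7 and DMD_KD between -26.5 and 1.21. DMD_KD lay 17.9 units nearer to WT_ND than DMD_ND did (exact two-sided permutation p = 0.00216, adjusted p = 0.00952 over 18 library comparisons, the smallest p the 924 relabellings can give). DMD_KD replicate 3 stood apart on the second component (13.5% of the variance) at -57.5, where the other DMD_KD libraries lay between -10.2 and 10.2. Reads from the mitochondrial chromosome made up 23 ± 2.42% (SD, n = 4) of WT_ND, 13.1 ± 0.789% (n = 6) of DMD_ND and 15.6 ± 1.01% (n = 6) of DMD_KD libraries. That share was lower in DMD_ND than in WT_ND (exact permutation p = 0.00476) and higher in DMD_KD than in DMD_ND (exact permutation p = 0.00216), each with an adjusted p = 0.00952.

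**Figure D1:**
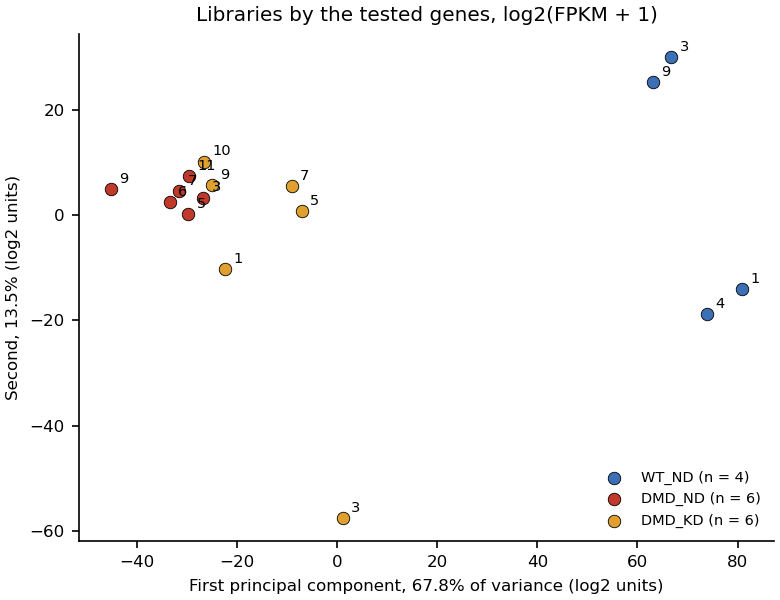
First against second principal component of log2(FPKM + 1) over the tested genes, in log2 units, 1 point per library with its replicate number, coloured by group. The 4 WT_ND libraries lie at 63 or above on the first component, every mutant library lies at 1.21 or below, and DMD_KD replicate 3 lies at -57.5 on the second.

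The first comparison, DMD_ND against WT_ND, asks what the Dmd mutation changed in muscle on the normal diet. Genes of connective tissue, inflammatory cells and muscle regeneration were higher in mutant muscle, and genes of mitochondrial energy metabolism, glycogen use and fast contraction were lower. RNA came from whole muscle pieces, so a change within fibres was not told apart from one in cell makeup. Of 12119 tested genes, 7967 differed (65.7%, limma, Benjamini-Hochberg adjusted p under 0.05), 3815 higher and 4152 lower in DMD_ND. Among these, 2916 differed at least 2-fold, 1690 of them higher and 1226 lower. The fold changes are relative to a scaling that holds the typical gene level between libraries. Scaled instead to an equal total per library (TPM), the median gene shifted by 0.83 on the log2 scale, and the calls split into 8564 higher and 720 lower of 9284. Restricting the test to a mean of at least 5 FPKM left 4361 calls, 1477 higher and 2884 lower.

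On the log2(FPKM + 1) scale, which holds down the change of genes near 0 in WT_ND, the largest rises were in Ankrd1, a stretch-responsive ankyrin repeat protein of muscle, from 7.22 ± 5.54 FPKM (SD, n = 4) to 435.6 ± 111 (n = 6), a 62.4-fold change (log2 5.96, SE 0.36, adjusted p = 8.02e-10), and in the calcium-binding protein S100a4, 58.6-fold from 8.57 ± 2.38 to 553.8 ± 109 FPKM (log2 5.87, SE 0.19, adjusted p = 1.06e-12). Next came Spp1 (osteopontin, 41.6-fold), Ctxn3 (40.7-fold), the myoblast fusion factor Mymx (31.7-fold), the metalloproteinase inhibitor Timp1 (28.7-fold), the matricellular protein Postn (28.2-fold) and the small GTPase Rrad (26.3-fold). The Spp1 mean of 170.9 ± 294 FPKM (SD, n = 6) held 1 library at 771 FPKM, with the other DMD_ND libraries between 31.7 and 73.4. The fold change and rank of Spp1 rest in part on that library. The largest falls on that scale were in the transcription factor Barx2, 15.5-fold from 15.9 ± 6.31 to 0.034 ± 0.042 FPKM (log2 -3.95, SE 0.19, adjusted p = 5.3e-11), and in Aqp4, the water channel of the fibre membrane, 15.2-fold from 34.9 ± 10.6 to 1.36 ± 0.581 FPKM (log2 -3.92, SE 0.22, adjusted p = 3.15e-10). Prkaa2, a catalytic subunit of AMP-activated kinase, fell 12.5-fold, Zyg11b 11.8-fold, the calcium channel subunit Cacna2d1 10.4-fold, Unc5a 10.4-fold, Rhou 10.4-fold and Prima1, which anchors acetylcholinesterase, 8.98-fold. For each of these 16 genes all 6 DMD_ND libraries lay beyond all 4 WT_ND libraries. Chance gives that separation to 0.952% of unselected genes. These genes were picked from the called ones for their fold changes, so the separation adds no support.

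Matrix and inflammatory genes rose together. All 33 measured members of the extracellular matrix list were higher in DMD_ND (median log2 2.92, camera adjusted p = 2.68e-18; adjusted p = 0.0928 with an estimated correlation), among them Col1a1, a chain of type I collagen, 20-fold from 16.1 ± 5.11 FPKM (SD, n = 4) to 335.0 ± 67.2 (n = 6), and biglycan (Bgn), 16.4-fold. Markers of other cell types moved with them. All 21 macrophage markers were higher (median log2 2.78, camera adjusted p = 1.23e-10; adjusted p = 0.22 with an estimated correlation), including Tyrobp, 9.63-fold, and the complement gene C1qa, 8.49-fold. Of 13 markers of fibro-adipogenic progenitors, the connective tissue cells of muscle, 12 were higher and 1 was not called (median log2 2.19, camera adjusted p = 2.69e-06; adjusted p = 0.251 with an estimated correlation), with Dpt (dermatopontin) 8.12-fold higher. Of 14 cytokine and chemokine genes 12 were higher, none lower and 2 not called (median log2 1.73, camera adjusted p = 3.64e-05; adjusted p = 0.251 with an estimated correlation), among them the monocyte attractant Ccl2, 23.6-fold, and the macrophage growth factor Csf1, 4.41-fold. Of 17 interferon response genes 13 were higher, none lower and 4 not called (median log2 0.71, camera adjusted p = 0.00228; adjusted p = 0.274 with an estimated correlation), with the interferon-induced GTPase Gbp2 at 2.85-fold. Of 11 endothelial markers, 2 were higher, 3 lower and 6 not called (median log2 -0.03, camera adjusted p = 0.812), a median that turned positive under TPM scaling.

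Regeneration and denervation genes were also higher, as were genes of apoptosis, p53 and senescence. Of 12 cell cycle genes 8 were higher, 1 lower and 3 not called, and the list was not called (median log2 0.55, camera adjusted p = 0.0962). Of 16 muscle regeneration genes, 12 were higher, 1 lower and 3 not called (median log2 2.53, camera adjusted p = 7.47e-06; adjusted p = 0.22 with an estimated correlation). Perinatal myosin Myh8 rose 7.73-fold, from 4.27 ± 0.918 FPKM (SD, n = 4) to 39.5 ± 4.41 (n = 6), and the fusion factor Mymk 25.3-fold. Of 19 denervation and neuromuscular junction genes, 13 were higher, 2 lower and 4 not called (median log2 1.24, camera adjusted p = 0.00133; adjusted p = 0.251 with an estimated correlation), with the acetylcholine receptor subunit Chrna1 10.6-fold higher. Of 18 apoptosis, p53 and senescence genes, 15 were higher, 1 lower and 2 not called (median log2 0.86, camera adjusted p = 8.37e-05), the only list of this comparison still called with an estimated correlation (adjusted p = 0.0437). Its members include the cell cycle inhibitors Cdkn1a, 23.7-fold higher, and Cdkn2a, which had no read in any WT_ND library and stood at 19.1 ± 1.62 FPKM (SD, n = 6) in DMD_ND. Against a floor of 3 reads per WT_ND library, 0.188 FPKM, Cdkn2a was at least 102-fold higher, and the list's median was 0.86 with the gene at that bound; the floor covers counting error only.

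Energy metabolism genes were lower across lists, beside the lower share of mitochondrial reads in DMD_ND. All 20 fatty acid oxidation genes fell (median log2 -1.33, camera adjusted p = 9.77e-10; adjusted p = 0.22 with an estimated correlation). Examples are the acyl-CoA synthetase Acsl1, from 134.1 ± 17.5 FPKM (SD, n = 4) to 39.6 ± 2.88 (n = 6), the thiolase Acaa2, from 203.3 ± 38.9 to 56.8 ± 4.73, and the dehydrogenase Hadh, from 124.6 ± 14.1 to 39.3 ± 2.74. Of 31 oxidative phosphorylation genes 30 fell and 1 was not called (median log2 -1.30, camera adjusted p = 1.29e-09; adjusted p = 0.274 with an estimated correlation), with Sdha, a subunit of succinate dehydrogenase, 3.41-fold lower. All 13 mitochondrially encoded genes fell (median log2 -1.66, camera adjusted p = 2.9e-07; adjusted p = 0.274 with an estimated correlation), Mt-nd5 by 3.76-fold. Of 24 glycolysis and glycogen genes 23 fell and 1 was not called (median log2 -1.38, camera adjusted p = 1.64e-06; adjusted p = 0.297 with an estimated correlation), the phosphorylase kinase subunit Phkg1 by 4.81-fold. The 16 measured PPAR target genes, which respond to fatty acids, went both ways, with 4 higher, 9 lower and 3 not called (median log2 -0.63, camera adjusted p = 0.0935), a median that turned positive under TPM scaling. Fabp3, the muscle fatty acid binding protein, fell 4.14-fold and the uncoupling protein Ucp2 rose 3.91-fold. Under TPM scaling the medians were -0.33 for fatty acid oxidation, -0.29 for oxidative phosphorylation, -0.65 for mitochondrially encoded genes and -0.37 for glycolysis, each below the shift of 0.83 of the median gene.

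Contractile genes changed unevenly. Of 13 fast-twitch genes 11 fell and 2 were not called (median log2 -1.24, camera adjusted p = 0.00105; adjusted p = 0.442 with an estimated correlation; -0.22 under TPM scaling), Myh2 by 5.11-fold and Myh4 by 2.36-fold. These myosin genes are alike in sequence, and how reads matching several copies were counted is not given in the sources used here. Of 14 slow-twitch genes 3 rose, 6 fell and 5 were not called (median log2 -0.28, camera adjusted p = 0.43; positive under TPM scaling), with the cardiac-type calcium buffer Casq2 10.5-fold higher and the slow myosin light chain Myl3 5.85-fold lower. Of 16 calcium handling genes 1 rose, 12 fell and 3 were not called (median log2 -0.98, camera adjusted p = 0.0123; adjusted p = 0.442 with an estimated correlation; 0.03 under TPM scaling). The riser was sarcolipin (Sln), a small inhibitor of the calcium pump, from 26.2 ± 5.14 FPKM (SD, n = 4) to 646.5 ± 283 (n = 6), and the junctional protein Jph1 fell 2.98-fold. Of 15 genes of the dystrophin-associated complex 1 rose, 9 fell and 5 were not called (median log2 -0.50, camera adjusted p = 0.0387; adjusted p = 0.274 with an estimated correlation; 0.51 under TPM scaling), Nos1, the neuronal nitric oxide synthase, by 2.93-fold, while laminin Lama2 rose 2.32-fold. Camera called 19 of 36 lists here, and other splits of the same libraries, which keep part of the genotype difference, called up to 24. Counts adjusted over the list alone equalled those given for each list of this comparison, except that 13 regeneration genes were higher.

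**Figure D2:**
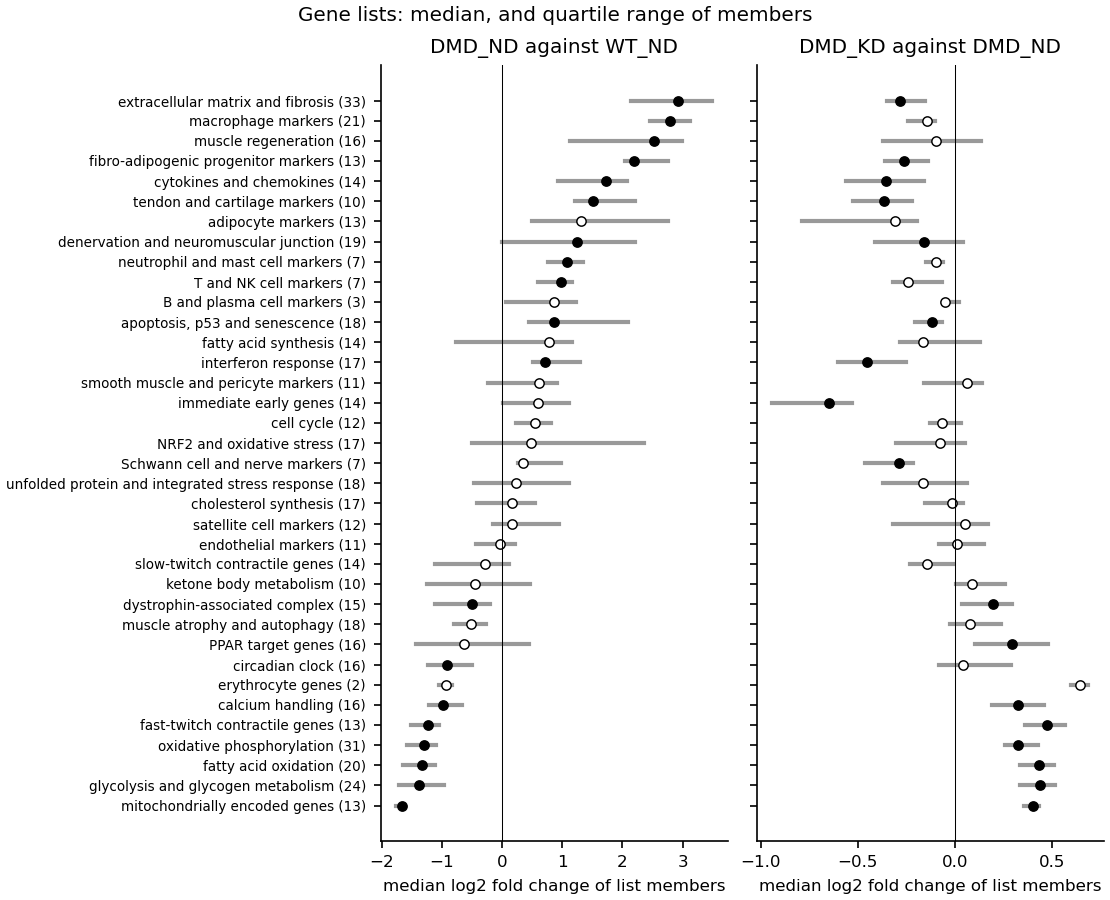
Median log2 fold change of each of the 36 gene lists, with the number of measured members in parentheses and grey bars for the quartile range of members, for DMD_ND against WT_ND and DMD_KD against DMD_ND. Filled points have a camera adjusted p under 0.05; matrix genes stand at 2.92 and -0.28, fatty acid oxidation genes at -1.33 and 0.43.

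The second comparison, DMD_KD against DMD_ND, asks what the diet changed in mutant muscle. A single gene passed the test: Fabp3, which carries fatty acids within the muscle fibre, was 2.09-fold higher on the diet, at 219.8 ± 41.6 FPKM (SD, n = 6) against 103.6 ± 9.25 (n = 6), with WT_ND at 437.5 ± 88.6 (n = 4). Its log2 fold change was 1.06 (SE 0.14, limma adjusted p = 0.00772), and all 6 DMD_KD libraries lay above all 6 DMD_ND libraries. Fabp3 (ENSRNOG00000012879) lies on chromosome 5, 142651956 to 142658718, in mRatBN7.2. The other 9 genes with the smallest p did not pass. They were the coenzyme A carrier Slc25a42 (log2 0.64), Vwa8 (0.56), the lipid droplet protein Plin5 (0.80), the enoyl-CoA isomerase Eci2 (0.46) and Nudt7 (0.70), each with an adjusted p = 0.132, and the chemokine Cxcl13 (-1.17), Crabp2 (-0.83), Hadh (0.51) and Tmem63b (0.45), each with an adjusted p = 0.14. At an unadjusted p under 0.05, 1727 of 12119 genes stood out where chance gives 606. An exact rank-sum test per gene called 0 genes, with an adjusted p = 0.147 for Fabp3. That test could hardly call a single gene. Chance separates 6 libraries fully from 6 in 0.216% of splits, the smallest p it can give, and Fabp3 already reached that. With the replicate number as a block, limma called 0 genes. Limma with weights per library, which gave DMD_KD replicate 3 a weight of 0.129, called 93 genes, 51 higher and 42 lower, and 28 with that library left out. Leaving out DMD_KD replicate 9 gave 7 calls and DMD_ND replicate 7 gave 2.

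**Figure D3:**
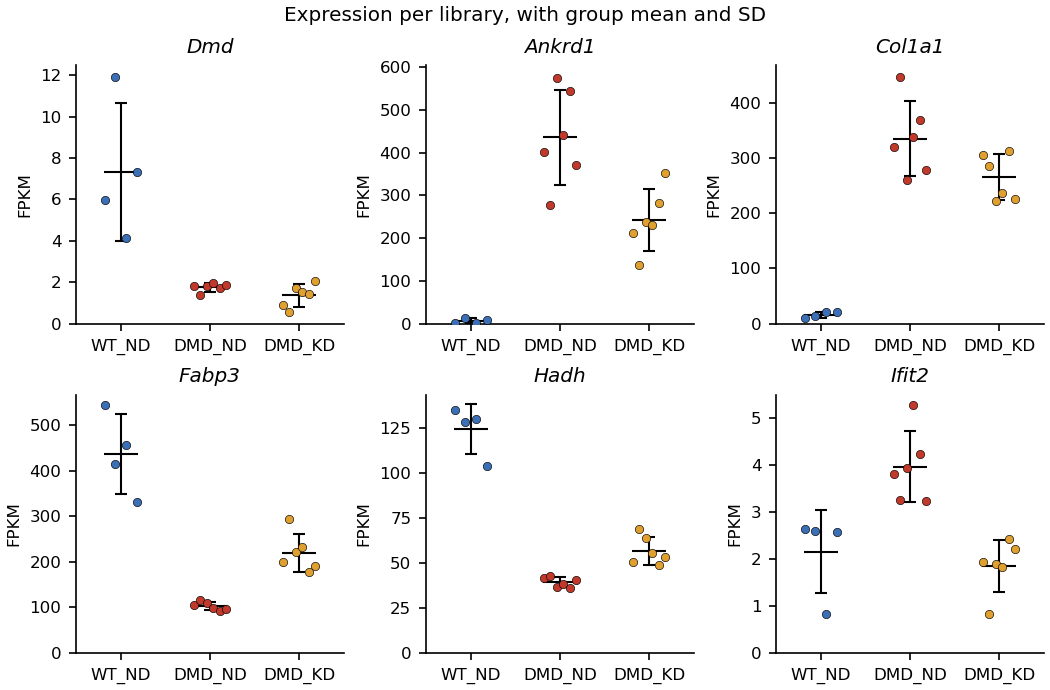
FPKM of Dmd, Ankrd1, Col1a1, Fabp3, Hadh and Ifit2 in each library (points), with the group mean and SD (bars). Fabp3 stood at 437.5 FPKM in WT_ND, 103.6 in DMD_ND and 219.8 in DMD_KD on average, and Ifit2 at 2.15, 3.95 and 1.85.

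Fatty acid oxidation genes were higher on average on the diet, as a group. All 20 fatty acid oxidation genes had a positive log2 fold change (median 0.43); none was called over all genes and 16 were when adjusted over the list alone. The camera adjusted p was 1.12e-15, with an adjusted p = 0.0858 with an estimated correlation. Relabelling the 12 mutant libraries gave an exact permutation p = 0.00216 (adjusted p = 0.0389) for the median, and without DMD_KD replicate 3 the median was 0.38 (exact permutation p = 0.00216). Hadh stood at 56.8 ± 7.96 FPKM (SD, n = 6) against 39.3 ± 2.74 (n = 6), Acaa2 at 90.4 ± 19 against 56.8 ± 4.73, and Decr1, which handles unsaturated fatty acids, at 56.6 ± 9.12 against 37.6 ± 4.04. Of 16 PPAR target genes, Fabp3 was called and 15 were not, and 7 were higher when adjusted over the list alone (median log2 0.30, camera adjusted p = 9.17e-07; adjusted p = 0.0858 with an estimated correlation; exact permutation adjusted p = 0.111). Among these, the malonyl-CoA decarboxylase Mlycd had a log2 fold change of 0.73 and the thioesterase Acot2, which is close in sequence to Acot1, of 0.44. The 14 fatty acid synthesis genes leaned lower and were not called as a list (median log2 -0.17, camera adjusted p = 0.448) or singly over all genes, and 1 was higher when adjusted over the list alone. The 10 ketone body genes were not called as a list (median log2 0.08, camera adjusted p = 0.0682) or singly over all genes or adjusted over the list alone, and the median turned negative under TPM scaling.

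Interferon response genes were lower on average on the diet, as a group. All 17 had a negative log2 fold change (median -0.45); none was called over all genes and 11 were lower when adjusted over the list alone. The camera adjusted p was 2.59e-09 (adjusted p = 0.0858 with an estimated correlation), and the exact permutation p of the median was 0.00216 (adjusted p = 0.0389), with a median of -0.43 without DMD_KD replicate 3. Usp18, a brake on interferon signalling that interferon itself induces, stood at 2.35 ± 0.293 FPKM (SD, n = 6) against 3.84 ± 0.549 (n = 6), Ifit2 at 1.85 ± 0.553 against 3.95 ± 0.755, and Cxcl10 at 0.612 ± 0.352 against 1.76 ± 0.869. Of 14 cytokine genes none was called and 4 were lower when adjusted over the list alone (median log2 -0.35, camera adjusted p = 5.37e-05; adjusted p = 0.33 with an estimated correlation), with Csf1 at 6.99 ± 1.11 against 10.9 ± 2.27 FPKM and Ccl2 at 11.2 ± 4.76 against 40 ± 40.6. That Ccl2 mean held 1 DMD_ND library at 122 FPKM.

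Energy, fast-twitch and matrix lists leaned towards wild type without a member called. In values as deposited, the 14 slow-twitch genes leaned away from it (median log2 -0.15, camera adjusted p = 0.279), with none passing when adjusted over the list alone. Under TPM scaling the slow-twitch median was 0.67 for the genotype and -0.41 for the diet. The median gene then shifted by 0.83 and -0.24, so the slow-twitch median lay below it in both comparisons, as in the deposited values. All 31 oxidative phosphorylation genes had a positive log2 fold change (median 0.33, camera adjusted p = 2.24e-10; adjusted p = 0.33 with an estimated correlation), with Sdha at 98.9 ± 12.4 FPKM (SD, n = 6) against 79.4 ± 9.55 (n = 6), beside the higher share of mitochondrial reads in DMD_KD. The 13 mitochondrially encoded genes had a median of 0.40 (camera adjusted p = 1.54e-09; adjusted p = 0.33 with an estimated correlation), 6 of them higher when adjusted over the list alone. Of these, Mt-co1 stood at 50100 FPKM in DMD_KD replicate 3 and between 24700 and 30000 in the other DMD_KD libraries. The 24 glycolysis genes had a median of 0.43 (camera adjusted p = 1.28e-08; adjusted p = 0.33 with an estimated correlation), and 1 was higher when adjusted over the list alone. The bisphosphatase Fbp2 stood at 102.5 ± 23.7 against 62.1 ± 14.8 FPKM. The 13 fast-twitch genes had a median of 0.47 (camera adjusted p = 3.58e-06; adjusted p = 0.33 with an estimated correlation), with Mylk2, the muscle myosin light chain kinase, at 371.1 ± 138 against 228.2 ± 65.4 FPKM, and none passed when adjusted over the list alone. All 33 matrix genes had a negative log2 fold change (median -0.28, camera adjusted p = 1.59e-06; adjusted p = 0.33 with an estimated correlation), with Postn at 44.4 ± 16.2 against 71.3 ± 15.7 FPKM and Col6a3 at 29.0 ± 4.61 against 36.9 ± 4.73, and none passed when adjusted over the list alone. The macrophage markers had a median of -0.15 (camera adjusted p = 0.0654) and the fibro-adipogenic markers of -0.26 (camera adjusted p = 0.0379; adjusted p = 0.546 with an estimated correlation), with none called over all genes or adjusted over the list alone. Camera called 17 of 36 lists, other splits of the 12 mutant libraries called up to 22, and an exact relabelling of the list medians called 2, fatty acid oxidation and interferon response. Under TPM scaling, which shifted the median gene by -0.24, their medians were 0.17 and -0.73, and some other medians shrank, to 0.06 for oxidative phosphorylation, 0.13 for mitochondrially encoded genes, 0.17 for glycolysis and 0.20 for fast-twitch genes.

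Diet and genotype fold changes ran in opposite directions across genes. Over the 12119 genes, Pearson's r was -0.69 and Spearman's rho -0.71, and 6769 of the 7967 genotype-called genes (85.0%) had a diet fold change of the opposite sign, a share that reached 88% in other relabellings of the mutant libraries (2 of 100 as high, the real one included) and averaged 82.4% with DMD_ND split; genes are not independent replicates. Fold changes of fatty acid oxidation genes went from a median of -1.33 to 0.43 and those of matrix genes from 2.92 to -0.28. The slope of the diet on the genotype log2 fold change was -0.18. Because both use the DMD_ND libraries, a negative value arises with no effect, and unchanged simulated groups gave a mean r of -0.36 with a range of -0.81 to 0.49, which holds the observed r. The covariance was -0.158, against -0.00986 in those simulations, a difference of -0.148. The simulations hold no genotype effect, so differences between mutant libraries along it are left out. Drawn relabellings of the mutant libraries, which keep that effect, reached a covariance of -0.141. With DMD_ND split so that the fold changes shared no library, r averaged -0.60 over 20 such splits (range -0.67 to -0.51) and the covariance averaged -0.148. Among all 924 relabellings of the mutant libraries, 11 gave an r as low (exact one-sided permutation p = 0.0119) and 1, the real one, a covariance as low (exact one-sided permutation p = 0.00108).

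**Figure D4:**
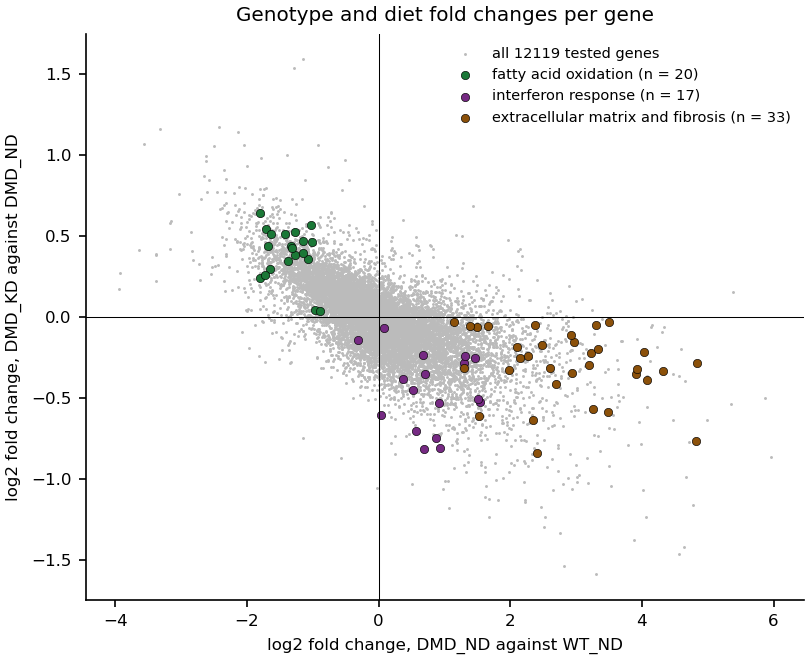
Log2 fold change of each of the 12119 tested genes for DMD_ND against WT_ND (x axis) and DMD_KD against DMD_ND (y axis), with fatty acid oxidation, interferon response and extracellular matrix genes coloured. The points run from upper left to lower right (r = -0.69), part of which comes from the shared DMD_ND libraries.

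The third comparison, DMD_KD against WT_ND, asks what still differed from wild type in mutant rats on the diet. Matrix genes stayed above wild type and fatty acid oxidation genes below it. Of 12119 genes, 7068 differed (58.3%), 3304 higher and 3764 lower, and 1957 by at least 2-fold, 1264 of them higher and 693 lower. All 33 matrix genes were higher (median log2 2.59, camera adjusted p = 7.61e-21; adjusted p = 0.0541 with an estimated correlation), Col1a1 at a log2 of 3.99 and Ankrd1 of 5.10 among the examples from the first comparison. All 20 fatty acid oxidation genes were lower (median log2 -0.91, camera adjusted p = 3.23e-08; adjusted p = 0.216 with an estimated correlation; -0.18 under TPM scaling), with Hadh at -1.12 and Acaa2 at -1.16; Eci2 at -0.55 (adjusted p = 0.000172) turned to 0.18 under TPM scaling. Fabp3 remained lower, by a log2 fold change of -0.99 (adjusted p = 4.28e-05), as did Plin5 at -1.24. Of 17 interferon genes 8 were higher, 1 lower and 8 not called (median log2 0.13, camera adjusted p = 0.123), with Usp18 at 0.39 (adjusted p = 0.0132) and Ifit2 at -0.12 (adjusted p = 0.629). Ccl2 stayed higher at 3.10 (adjusted p = 9.52e-06). Counts adjusted over the list alone equalled these.

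The calls of the third comparison overlapped those of the first. In both, 3198 genes were higher and 3512 lower than in WT_ND, 6710 in all, and none was called in opposite directions. Independent lists of these sizes would share 1040 higher and 1290 lower genes, and simulated unchanged groups against the same WT_ND libraries shared 0. Neither is a fair reference, since both comparisons use the same WT_ND libraries, and groups without a change have few calls to share. With WT_ND split so that each comparison had its own 2 libraries, 4437 to 5306 genes were shared. Under TPM scaling the third comparison called 7503 genes, 6930 higher and 573 lower, with the median gene shifted by 0.56, and a mean of at least 5 FPKM left 3950.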

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

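In this part, the tests for a mislabelled sample were chosen after the result was seen. Values stand here when 1 library's gap to the nearest of its group exceeded Dixon's 95% critical value in relation to the group's range. For genes, gap and range were taken on the log2(FPKM + 1) scale, while the values given are FPKM. Of 261 sets of values examined, 29 did so, where chance, at about 1 in 20 sets, gives about 13. Of the 29, 10 were in DMD_KD replicate 3.

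DMD_KD replicate 3 took 29.6% of its reads from the 10 most abundant genes (others of its group 21.4 to 24.0%) and 5.48% from the actin gene Acta1 (others 2.74 to 3.36%). It had 10605 genes at 1 FPKM or more, against 11306 to 11503, and a value of -57.5 on the second component, against -10.2 to 10.2. In FPKM, its Mt-nd5 at 3420 (others 2200 to 2540) and Mt-co1 at 50100 (24700 to 30000) were high. Its share of mitochondrial reads was not, at 16.5% within a group range of 14.4 to 17%. Barx2 stood at 0.5 FPKM (0.065 to 0.166) and Unc5a at 0.746 (0.191 to 0.356). Postn at 14.3 FPKM (40.5 to 58.2) and Ifit2 at 0.823 (1.82 to 2.43) were low.

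Among DMD_ND libraries, replicate 9 had a first component of -45.1 (others -33.4 to -26.7), Myh4 at 1290 FPKM (2170 to 2580), Mylk2 at 114 (202 to 284), Fbp2 at 33.9 (57.8 to 72.3) and Eci2 at 18.4 (20.2 to 21.3). Replicate 11 had Spp1 at 771 FPKM (31.7 to 73.4) and Ucp2 at 30.4 (17.8 to 21.3), and replicate 7 had Ccl2 at 122 (15.1 to 31.7). In DMD_KD replicate 10, Acot2 stood at 7.25 FPKM (4.5 to 5.33).

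Among WT_ND libraries, replicate 3 had the desaturase Scd at 8.57 FPKM (others 0.326 to 0.585), the fat cell hormone Adipoq at 14.3 (2.23 to 3.13) and Ctxn3 at 1.88 (0.207 to 0.289), and low values of Chrna1 at 3.51 (5.16 to 5.47), the clock-controlled factor Dbp at 56.5 (72.0 to 72.7) and Tmem63b at 25.6 (31 to 32.2). Replicate 1 had Dpt at 11.7 FPKM (20.6 to 22.9) and Nos1 at 11.6 (7.67 to 8.16). Replicate 9 had Mymx at 2.51 FPKM (0 to 0.0961), and replicate 4 had Ifit2 at 0.833 (2.56 to 2.63).

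DMD_KD replicate 3 shared its end of the second component with WT_ND replicates 1 and 4 (-14 and -18.8, against 30.1 and 25.3 in replicates 3 and 9), and fast-twitch genes (median percentile of the component's gene weights 2.91) and regeneration genes (5.59) lay at that end. Dmd argues against wild-type and mutant samples mislabelled for each other, at 0.546 FPKM in DMD_KD replicate 3, 5.95 in WT_ND replicate 1 and 4.13 in replicate 4, with no mutant library above 2.04. A wrong diet label of replicate 3 is not decided: Fabp3, called also without that library, stood there at 294.1 FPKM and at 92.1 to 116.8 in DMD_ND, but the library also lay nearest to WT_ND on the first component (1.21, other DMD_KD libraries up to -7.01), where Fabp3 is higher. A trend with gene length as the whole cause is argued against too. Removing each library's trend moved the deviation of DMD_KD replicate 3 from its group mean on this component only from -49.9 to -44.5. The other DMD_KD libraries then lay between -2.92 and 15.9. The Dixon ratio of DMD_KD replicate 3 went from 0.699 to 0.688, still beyond the critical value. A shrinkage shared by all libraries would leave that ratio unchanged, so the ratio alone does not decide it. A larger share of muscle fibre RNA stays open. Such a share would lower markers of all other cells alike. Of 10 such lists, 0 lay below the other DMD_KD libraries, 1 above and 9 inside their range, which neither excludes it nor bears it out. No other biological explanation was tested, because the labels name nothing that sets these libraries apart.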

How the results depend on the processing

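Limma voom on recovered reads, plain FPKM per 1e6 assigned reads, the 3 libraries left out together, weights without DMD_KD replicate 3, the exact relabelling of list medians and list tests under TPM and plain FPKM were tests chosen after seeing the data. Genotype calls numbered 7967, between 7413 (without WT_ND replicate 1) and 8495 (without DMD_KD replicate 3) with 1 library left out; they moved by over 1.5 times only under a mean of at least 5 FPKM (4361, fewer genes tested) and a 2-fold threshold (2916, by construction). For DMD_KD against WT_ND the 7068 calls ranged from 6351 to 7731 in the same way, with 3950 and 1957 under those settings. The diet's 1 call became 2 with only both groups fitted, 3 with DMD_KD replicate 3 and WT_ND replicates 1 and 4 left out, 93 with weights per library, 28 with weights and without DMD_KD replicate 3, and 0 in the exact rank-sum test. The smallest p that the rank-sum test can give hardly lets a single gene pass after adjustment. With 1 library left out it ranged from 1 to 7 (without DMD_KD replicate 9), with 2 without DMD_ND replicate 7; Fabp3 was among the calls each time. Beyond that limit of the rank-sum test, the cause of these moves was not tested. Weights brought in 9 fatty acid oxidation genes, 3 interferon response genes, 2 cytokine genes (Cxcl10 in both) and, beside Fabp3, 2 PPAR targets; of the first 3 groups 5, 2 and 0 stayed without DMD_KD replicate 3. Voom called 7802, 1 and 6920 genes.

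TPM and plain FPKM shifted the median gene of DMD_ND against WT_ND by 0.83 and 0.64, of DMD_KD against DMD_ND by -0.24 and -0.19 and of DMD_KD against WT_ND by 0.56 and 0.43, as values scaled to a total do when abundant transcripts take a different share. With TPM, 5704 of the 7967 genes called by genotype were again called, counted whatever their direction. Lower calls numbered 4152 as deposited and 720 with TPM, and higher calls 3815 and 8564. Part of the 5704 genes must therefore have changed direction. Eci2, lower in DMD_KD than in WT_ND by -0.55, became 0.18 with TPM and 0.09 with plain FPKM, and was not called in either. The replicate number as a block gave 5852, 0 and 5190 calls for the 3 comparisons. Same-numbered libraries did not as a rule deviate together (correlations from -0.66 to 0.41 over 9 pairs, 2 of them above 0.1, and 2 of 12 libraries closest to their own number). This gives no sign of a general pairing by number. The labels do not say what the numbers mean, and so few pairs cannot exclude a pairing.

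Lists depended most on the correlation between genes. With it estimated, camera called 1, 0 and 1 lists in place of 19, 17 and 16, fry called 32, 4 and 31, and exact relabelling called 2 for the diet. With 1 library left out the counts stayed between 18 and 20, between 16 and 23 (the last without DMD_KD replicate 3) and between 16 and 17. The correlation of diet and genotype fold changes ranged from -0.72 to -0.63 with 1 library left out, and was -0.62 with voom, -0.60 with DMD_ND split and -0.75 over genotype-called genes. Of the diet's results for named genes under these settings, 34 newly passed and 2 no longer passed, against 2 no longer passing for the genotype; of the lists, 29 and 64 for the diet and 20 and 29 for the genotype. Depth limits genes with few reads. The simulated recovery of 1.5-fold changes was 59.7% for the diet, with independent noise and an easier cutoff than the real comparison had.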

Other observations

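In this part, the tests of the shared DMD_ND libraries, of DMD_KD replicate 3 as the source of the opposite fold changes, of a lower share of other cells, of the relabelled correlation and of leftover medians against all lists were chosen after the result was seen. Fat-related genes of mutant muscle went in both directions. Of 13 adipocyte markers, 10 were higher in DMD_ND than in WT_ND, 2 lower and 1 not called, with the same counts adjusted over the list alone (median log2 1.30, camera adjusted p = 0.0662). Adipsin (Cfd) rose 12.3-fold, from 11.3 ± 4.65 FPKM (SD, n = 4) to 159.6 ± 92.9 (n = 6), while the lipid droplet protein Plin4, which muscle fibres also make, fell 3.15-fold. Of 14 fatty acid synthesis genes 8 were higher, 4 lower and 2 not called, with the same counts adjusted over the list alone (median log2 0.79, camera adjusted p = 0.316). The desaturase Scd rose 15.6-fold (log2 3.96, and 4.64 without WT_ND replicate 3, where it was high) and Dgat2, which makes triglycerides, fell 4.46-fold. On the diet, Plin4 stood at 44.3 ± 10.4 against 28.5 ± 3.22 FPKM (limma adjusted p = 0.14), and the fat cell genes Retn at 3.14 ± 1.62 against 10.7 ± 7.93 (adjusted p = 0.14) and Adipoq at 22 ± 14.3 against 46.9 ± 30.8 (adjusted p = 0.328).

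Single stress, clock and atrophy genes differed by genotype, while of these lists only the clock genes were called. The metal-binding metallothionein Mt2A rose 25.6-fold (limma adjusted p = 9.71e-08) and mitochondrial superoxide dismutase Sod2 fell 3.14-fold, in a list of 17 oxidative stress genes with 8 higher, 5 lower and 4 not called, and 9 higher when adjusted over the list alone (median log2 0.49, camera adjusted p = 0.138). Of 16 circadian clock genes 2 were higher, 13 lower and 1 not called, with the same counts adjusted over the list alone (median log2 -0.92, camera adjusted p = 0.00805; adjusted p = 0.0928 with an estimated correlation; -0.05 under TPM scaling). Ciart fell 5.41-fold and Dbp 3.98-fold, and the labels give no time of day of sampling. Of 18 atrophy and autophagy genes 2 were higher, 11 lower and 5 not called, with the same counts adjusted over the list alone (median log2 -0.52, camera adjusted p = 0.0618; 0.42 under TPM scaling). Gadd45a rose 8.07-fold and myostatin (Mstn), which restrains muscle growth, fell 3.37-fold. On the diet none of these lists was called, and Gadd45a stood at 56.1 ± 23.3 FPKM (SD, n = 6) against 109.7 ± 28.0 (n = 6, adjusted p = 0.232), the ubiquitin ligase Fbxo32 at 29.5 ± 4.20 against 16.8 ± 5.94 (adjusted p = 0.19), Chac1 at 13.6 ± 8.41 against 5.87 ± 2.47 (adjusted p = 0.204) and haem oxygenase Hmox1 at 17.5 ± 4.54 against 37.9 ± 20.6 (adjusted p = 0.235). The 14 immediate early genes, which respond to handling within minutes, had a median diet log2 fold change of -0.65 (camera adjusted p = 0.000191; adjusted p = 0.33 with an estimated correlation), with 1 lower when adjusted over the list alone and Nr4a3 at 1.09 ± 0.387 against 3.33 ± 0.795 FPKM.

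Chance can be excluded for the number of genes called by genotype (7967, highest of the other splits 3888, 1 of 100 as high) and for DMD_KD against WT_ND (7068, highest other 4746, 1 of 100). It is not clearly excluded for the diet's count of 1 called gene, since 4 of 100 splits called as many (highest other 1). So few drawn splits give that share only roughly. The count holds for a call of any gene, so it does not test Fabp3 itself. The negative correlation of diet and genotype fold changes (-0.69) was reached by 2 of 100 relabellings, the real one included (lowest other -0.74). That makes chance less likely there but does not exclude it. Unchanged simulated groups reached -0.81, so the correlation alone does not show an effect. Chance cannot be excluded for the number of lists called, which was 19 for the genotype (highest other 24, 27 of 100 as high), 17 for the diet (highest other 22, 16 of 100) and 16 for DMD_KD against WT_ND (highest other 20, 20 of 100). For the comparisons with WT_ND these splits cannot decide the question. None can share the WT_ND libraries in proportion between its sides, so each keeps part of the genotype difference.

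The diet may have moved mutant muscle part of the way towards wild type, with Fabp3 the only gene called, a hypothesis found and tested on the same data. The shared DMD_ND libraries as its whole cause are argued against by the splits of DMD_ND, whose mean covariance of -0.148 no other relabelling reached (exact one-sided permutation p = 0.00108), and DMD_KD replicate 3 by the covariance without it (exact one-sided permutation p = 0.00216). A lower share of cells other than fibres in DMD_KD stays open, since endothelial and smooth muscle medians lay above those of fibro-adipogenic and macrophage markers by 0.24 (exact two-sided permutation p = 0.0671, and 0.251 without DMD_KD replicate 3). Of these lists' most abundant genes, picked after their values were seen, Gsn stood at 541.5 ± 139 FPKM (SD, n = 6) in DMD_KD and 852.8 ± 272 (n = 6) in DMD_ND, C1qb at 59.6 ± 14.5 and 62.2 ± 11.3, Acta2 at 52.8 ± 13.2 and 56.8 ± 11.3 and Pecam1 at 17.6 ± 1.99 and 19 ± 4.14. WT_ND muscle held 13 of the 13 fibro-adipogenic and 11 of the 21 macrophage markers at 1 FPKM or more, so a change in fibres cannot be told apart from one in cell makeup.

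Fatty acid oxidation genes were higher and interferon response genes lower on the diet, and whether by more than a general reversal of the genotype change stays open. After the fitted multiple of the genotype change was removed, medians of 0.20 (exact permutation p = 0.026) and -0.24 (exact permutation p = 0.0455) were left, but these lists were picked for their diet change, and against the largest of all 36 lists the exact permutation p was 0.35 and 0.687. DMD_KD replicate 3 alone is argued against for both lists, since without it the full medians were 0.38 and -0.43, from 0.43 and -0.45 (exact permutation p = 0.00216 each, and 0.0433 and 0.0758 against the largest of all lists, which allows for the picking). More mitochondria per fibre stays open too, as fatty acid oxidation stood above oxidative phosphorylation genes by 0.11 (exact permutation p = 0.422, and 0.0411 without DMD_KD replicate 3), and so do fewer macrophages, from whose markers the interferon genes differed by -0.30 (exact permutation p = 0.147). Fatty acid sensing by PPAR factors, which act on Fabp3 and Plin5, is a candidate explanation that was not settled, with a median of 0.20 left in the PPAR list (exact permutation p = 0.113, and 0.0563 without DMD_KD replicate 3).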
